A study of Mus musculus with 9 samples.

How the data were processed

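RNA from RAW264.7 macrophages was hybridised to Illumina mouse whole-genome bead arrays, with 3 control, 3 NFAT5 knock-down and 3 NFAT5 decoy samples. Samples were grouped by their titles and source names. A characteristics field has a heading that names a cytokine treatment but holds the text on the knock-down and the decoy, and it was not used for grouping. Both deposited tables hold all 9 arrays. The first holds raw probe intensity values as whole numbers, which the authors deposited without background subtraction or scaling, as the values themselves show. It has no detection p-values and no control probes, and 2042 blank rows at its end were dropped. The second holds log2 values processed by the authors. Its columns share nearly the same quantiles and rank the probes as the raw columns do (rank correlation at least 0.99995), with array medians from 7.299 to 7.304. R 2.9.1 is named in the submitters' processing notes, and the normalization method is not given in the sources used here.

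The values used here start from the raw intensities. The design, fixed before the data were examined, called for background correction from detection p-values. As the table has none, its written fallback was used: normexp background correction with an offset of 50, log2 and quantile normalization in limma 3.58.1 (R 4.3.3). A probe was kept if it exceeded the array's median probe on at least 3 arrays, which left 27062 of 45281 probes. Gene symbols came from the platform annotation supplied with the series. It gave 1 symbol to 34885 probes, several to 18 and none to 10378, and 0 symbols changed when brought up to date through the reference gene table. Each gene was represented by its brightest kept probe, by the mean over 9 arrays, and probes without a single symbol stood alone. This left 18830 features, 13716 of them genes with a symbol.

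A background limit was chosen after the data were seen, as the mode of an array's log2 signals plus 3 SD of their lower side. Where no array of the dimmer group exceeded it, the change is given as "at least" a fold. That bound sets the brighter group's mean against the mean of, per array, the higher of the lowest signal above background and the probe's own signal. The number of arrays limits the precision. Signals of 60000 units or more were taken as saturated, a limit chosen after the data were seen (the highest signals of the 9 arrays were 66075 to 70674). They were reached by 128 to 140 probes on the control arrays, 7 to 52 on the knock-down and 11 to 34 on the decoy arrays. A fold is given as "at least" where every array of the brighter group reached the limit, and folds where some did are understated to an unknown degree if the signal was cut there. Other probes of a gene were compared only where above background on at least 3 arrays.

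A linear model over all 9 arrays with 3 group means was fitted with limma's lmFit and eBayes. It gave knock-down against control, decoy against control and knock-down against decoy, and a moderated F test over the 3 groups. A feature was called at a Benjamini-Hochberg adjusted p below 0.05, and all tests were two-sided. Of 30 gene lists, fixed at the same time as the design, 29 had at least 5 measured members and were tested with camera (preset correlation 0.01). Epithelial markers, with 3 measured members, were not tested. With an estimated correlation no list was called in any comparison by camera, and 4, 2 and 4 lists had an unadjusted p below 0.05 for knock-down against control, decoy against control and knock-down against decoy. By fry, which does not compare a list with other genes, 23, 20 and 8 lists were called.

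Genes named in the text follow a rule fixed with the design. It takes Nfat5, the 8 largest rises and 8 largest falls per comparison among called genes whose 3 arrays do not overlap the other 3 (chance gives 10% of genes without overlap), up to 4 members of smallest p in each list with a called member, and for the overlap 8 shared rises, 8 shared falls and up to 4 genes of opposite sign. Clone-type names were counted and not named. Of the list members this rule takes, those printed are a part that was picked after their values were seen.

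The scripts were tested on simulated data. With 200 of 18830 features changed in a simulated knock-down against control, 20% of the 1.5-fold and 84% of the 2-fold changes were recovered, with 5 false calls. A list raised by 0.5 in log2 was the 1 list called. Shared controls were simulated 100 times. Alternatives covered the normalization, the authors' values, the probe filter, the value of a gene, a replicate block, array weights, each array left out in turn and the groups in the fit.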

Results

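Gene expression was measured in RAW264.7 cells, a mouse macrophage line, on 9 Illumina whole-genome bead arrays. NFAT5 is a transcription factor known for its role in the response to high salt. Untreated cells formed the control group. A second group stably carried a short hairpin RNA against Nfat5 (knock-down), and the third stably carried oligonucleotides with the NFAT5 binding sequence, which compete for the protein (decoy). Each group had 3 arrays. The aim given by the submitters was to find transcripts controlled by NFAT5, by combining both ways of lowering its activity. No group analysed here carried an unrelated hairpin or oligonucleotide, so each comparison with control also contains whatever transfection and selection did to the cells. The labels do not say whether the 3 samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

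The control arrays stood apart from both treated groups in signal and in spread. The upper quartile of their signal was 319, 336 and 330 units, against 257, 241 and 209 in the knock-down and 237, 236 and 214 in the decoy group. Between 34.5% and 36.8% of the probes were above background on the control arrays, 21.5% to 27.0% on the knock-down arrays and 24.6% to 27.1% on the decoy arrays. The median within-group SD was 0.091 in log2 for control, 0.22 for knock-down and 0.18 for decoy (n = 3 each). The first principal component held 65.5% of the variance and placed the 3 control arrays between -52.4 and -51.6, and the 6 treated arrays between 9.85 and 47.5.

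Nfat5 itself was lower in both treated groups on its brightest probe. The level was 11.46 ± 0.11 (log2, SD, n = 3) in control, 10.44 ± 0.061 in the knock-down and 10.98 ± 0.088 in the decoy cells. That is 2.04-fold lower in the knock-down (limma adjusted p = 1.89e-05) and 1.40-fold lower in the decoy (adjusted p = 0.0106, and 0.0673 without control replicate 1). The knock-down lay 1.46-fold below the decoy (adjusted p = 0.0355), a call that was lost under 12 of the alternative settings. After normalization the next-brightest probe, also above background on all 9 arrays, went the other way. It was 8.58 ± 0.14 in control, 9.22 ± 0.12 in the knock-down and 9.30 ± 0.062 in the decoy, 1.56-fold and 1.65-fold higher (adjusted p = 0.00153 and 0.00107 over all probes). Its raw signal did not rise: it was 752, 685 and 625 units in control, 596, 489 and 390 in the knock-down. In the decoy it was 640, 569 and 509. The rise thus appears only after arrays of unequal brightness were normalized. In normalized values the fall of Nfat5 therefore rests on 1 of the 2 probes with signal. Its 2 other probes were not above background on any array. The mean over all its probes, which includes those 2, showed no fall.

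**Figure D1:**
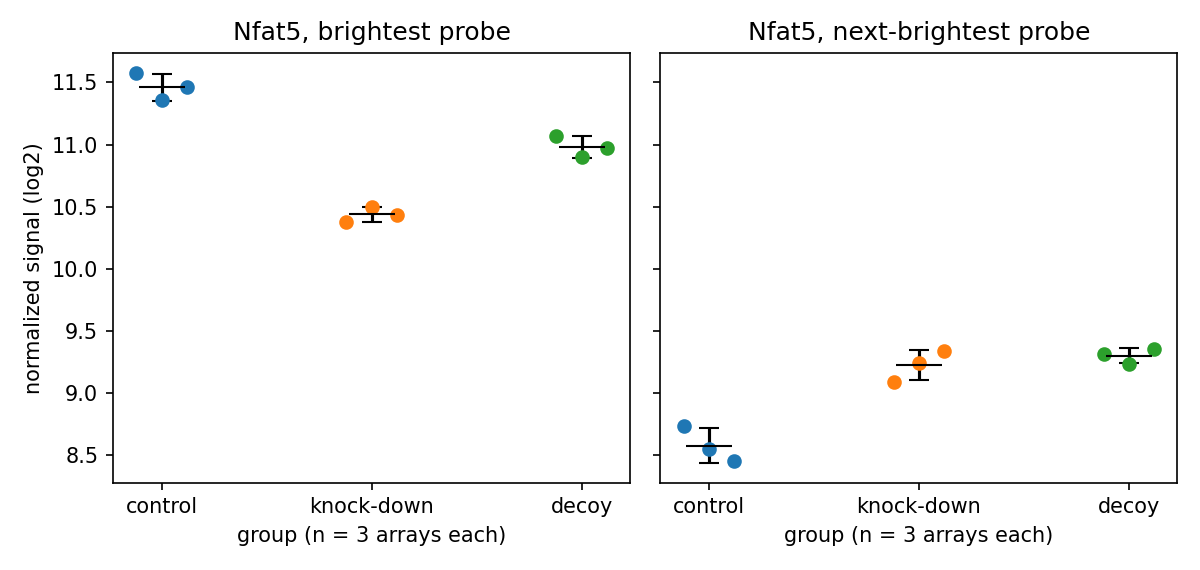
Normalized log2 signal of the 2 Nfat5 probes above background, on each array (points), with the mean and SD of each group (bars, n = 3). The brightest probe falls from 11.46 in control to 10.44 in the knock-down and 10.98 in the decoy, while the next-brightest probe rises from 8.58 to 9.22 and 9.30.

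The first comparison asked which genes differed between knock-down and control cells. Among the largest rises were Zc3h13, a factor of the RNA methylation complex (at least 8.63-fold, not above background in control), Ezh2, a histone methyltransferase (8.61-fold), and Ifi207, an interferon-inducible gene (6.74-fold). They were followed by the RNA-binding protein genes Hnrnpa2b1 (6.29-fold), Srek1 (6.19-fold) and Hnrnpk (5.68-fold), and by Pdpk1 (6.02-fold) and Usp37 (5.77-fold). The largest falls were in Ptpre, a protein tyrosine phosphatase (13.9-fold), Ndrg2 (11.1-fold), Bcl2a1b, an anti-apoptotic gene (9.09-fold), Wdr89 (8.78-fold) and Mcm7, a helicase subunit of DNA replication (8.24-fold). The others were COX2 (10.8-fold), ND1 (8.16-fold) and ATP6 (7.95-fold), which mitochondrial DNA encodes. The other probes of several of these genes did not share the change. Another probe was called in the opposite direction for Ezh2 (-0.45 in log2), Hnrnpa2b1 (-1.44) and Mcm7 (2.04), and for 1 of the 2 other probes of Ptpre and of Hnrnpk.

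In all, 8917 of 18830 features (genes, or probes without a single gene symbol) passed an adjusted p of 0.05, of which 4570 were higher and 4347 lower in the knock-down. A change of at least 2-fold was seen in 792 that rose and 1183 that fell. With arrays scaled to a common median in place of quantiles the split was 1578 higher and 9065 lower, and the median of all features moved by -0.43 in log2. Of 1170 genes with both of their 2 brightest probes called, 480 (41.0%, 95% exact binomial interval 38.2 to 43.9) had them in opposite directions. This interval and those of the other comparisons treat genes as independent, which genes on the same arrays are not.

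Interferon-stimulated genes were the 1 list that was called higher in the knock-down. Of 44 measured members 25 rose and 2 fell, and 29 passed when adjusted over the list alone (median log2 change 0.57, camera adjusted p = 2.78e-05). The adjusted p was 0.206 with an estimated correlation. Usp18, which removes the ubiquitin-like protein ISG15, rose 4.66-fold and its other probe also rose. Eif2ak2, the kinase PKR, rose 4.00-fold, Parp14 3.98-fold and the antiviral gene Rsad2 3.75-fold. Other immune lists were not called. Among chemokines, 5 of 14 rose and 2 fell (adjusted p = 0.604), with Cxcl10 2.77-fold and Ccl4 2.46-fold higher and Cxcl14 2.29-fold lower. MHC class I genes had 10 of 18 members higher and 2 lower (adjusted p = 0.299).

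Several lists of housekeeping and stress genes were called lower in the knock-down. Of 46 cytosolic ribosomal protein genes 24 fell and 4 rose (median -0.43, camera adjusted p = 0.000262, adjusted p = 0.303 with an estimated correlation), among them Rps21 (at least 3.29-fold, saturated on all control arrays) and Rpl32 (3.20-fold, saturated on 2 control arrays). The next-brightest probes of the 13 ribosomal genes with 2 probes above background had a median of 0.0256 (5 fell and 2 rose), against -0.475 on the brightest. Of 50 oxidative phosphorylation genes 24 fell and 11 rose (median -0.36, adjusted p = 0.000677, adjusted p = 0.0825 with an estimated correlation). In its 17 genes with 2 probes the median was -0.15 on the brightest and -0.563 on the next-brightest. Ndufb10, of complex I, fell 5.14-fold on its brightest probe and also on its other probe. Sdhd fell 5.03-fold, Cox6c 4.96-fold and Atp5a1 3.97-fold. Heat shock genes had 7 of 15 lower and 1 higher (median -0.43, adjusted p = 0.0226), and NRF2 targets had 9 of 18 lower and 2 higher (median -0.42, adjusted p = 0.0283). Both had an adjusted p of 0.303 with an estimated correlation, and neither was called without knock-down replicate 3 (adjusted p = 0.0526 each), the array with the lowest upper quartile of signals. The same held with the mean over the probes of a gene (adjusted p = 0.183 each) and with only probes above background on at least 3 arrays (adjusted p = 0.0652 and 0.134). The median of the NRF2 targets was -0.254 without knock-down replicate 1. Hspe1 fell 3.25-fold, and Hspd1 fell 3.13-fold while its other probe was called higher. Ftl1, the ferritin light chain, fell at least 4.29-fold (saturated on all control arrays), Tkt 2.85-fold and Prdx1 2.52-fold (saturated on 2 control arrays).

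Neither list of known NFAT5 targets was called by camera, which compares a list with other genes. By fry, which tests against no change, the osmoprotective list was lower (adjusted p = 0.000745) and the inflammatory list higher (adjusted p = 0.0021). Fry called 23 of the 29 lists in this comparison. Of 10 osmoprotective targets 2 rose and 4 fell (median -0.41, camera adjusted p = 0.174, 8 passing when adjusted over the list alone). S100a4 fell 6.12-fold, Akr1b8 2.82-fold and Pnpla6 1.52-fold, whereas Slc6a12, the betaine transporter and a classical target, rose 1.62-fold. Of 10 inflammatory targets described in macrophages 4 rose and 1 fell (adjusted p = 0.513), with Vegfc 2.74-fold higher. Ccl2 was lower (adjusted p = 0.000121) and was not above background on any knock-down array, so no fold is given.

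Genes of cell growth and survival changed in both directions. Of 35 cell cycle genes 9 rose and 12 fell (adjusted p = 0.604), with Ccne2 4.59-fold higher and Bub1b 3.19-fold and Pcna 2.74-fold lower. Of 21 pro-apoptotic genes 8 rose and 5 fell, and of 15 anti-apoptotic genes 4 rose and 4 fell (adjusted p = 0.604 and 0.671). The death receptor Fas rose 2.85-fold, the p53 antagonist Mdm2 2.39-fold and the pro-apoptotic Bcl2l11 2.10-fold. Bcl2a1d, whose probes both fell, was 6.32-fold lower and Mcl1 2.76-fold lower. Bcl2l2 was 2.00-fold higher, with 2 of its 3 other probes called lower. Atf4, of the amino acid response, fell 5.22-fold. Among macrophage identity genes 7 of 27 rose and 9 fell (adjusted p = 0.485), with Tyrobp 5.30-fold and Sirpa 2.88-fold lower and Lyz2 2.18-fold higher (saturated on 2 knock-down arrays). Another probe of Sirpa and of Lyz2 was called in the opposite direction, and the mean over the probes of Lyz2 was not called (adjusted p = 0.379). Among markers of other cell types, Acta2 of fibroblasts rose 3.11-fold and S100a8 of neutrophils 3.15-fold, and neither list was called (adjusted p = 0.299 and 0.979). Under median scaling the rises of Acta2, Bcl2l11, Bcl2l2, Ccl4, Fas, Lyz2, Mdm2, Slc6a12 and Vegfc were no longer called (differences of -0.314 to 0.556 in log2 there), nor was the fall of the heat shock list.

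The second comparison set the decoy against control. The largest rise was in Scn11a, a sodium channel gene, at 16.2-fold, followed by Ezh2 (7.01-fold), Hnrnpa2b1 (6.78-fold), Zc3h13 (at least 5.34-fold), Ifi207 (5.53-fold), Ddx5, an RNA helicase (5.46-fold), Srek1 (5.32-fold) and Hnrnpk (5.24-fold). The largest falls were in Bcl2a1b (8.17-fold), Ptpre (6.34-fold), Wdr89 (5.90-fold), COX2 (5.75-fold), Yipf2 (5.71-fold), Bcl2a1d (5.56-fold), Mcm7 (5.40-fold) and Hspb7 (5.36-fold). Another probe of Hnrnpa2b1, of Mcm7 and 1 of the 2 other probes of Ptpre were called in the opposite direction. In all, 6530 features passed, 3174 higher and 3356 lower. Under median scaling the split was 1314 higher and 8090 lower, with the median of all features at -0.37. Of 726 genes with both brightest probes called, 252 (34.7%, interval 31.2 to 38.3) had them in opposite directions.

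Interferon-stimulated genes were again higher, with 26 of 44 members up and 2 down (median 0.62, camera adjusted p = 1.71e-07, adjusted p = 0.167 with an estimated correlation). Usp18 rose 5.13-fold on its brightest probe and also on the other, Rsad2 4.36-fold, Igtp 3.75-fold and Parp14 3.43-fold. Ribosomal protein genes were lower, with 19 of 46 down and 2 up (median -0.30, adjusted p = 0.00137, adjusted p = 0.533 with an estimated correlation). Their next-brightest probes had a median of 0.00274 in 13 genes (3 fell and 2 rose), against -0.267 on the brightest. Oxidative phosphorylation genes had 21 of 50 down and 7 up (median -0.098, adjusted p = 0.0317, adjusted p = 0.167 with an estimated correlation), with Ndufb10 4.00-fold and Cox6c 3.36-fold lower. In its 17 genes with 2 probes the brightest had a median of 0.101 and the next-brightest of -0.485. That list was not called without decoy replicate 2 (adjusted p = 0.0669), or with only probes above background on at least 3 arrays (adjusted p = 0.156). Its median was -0.153 without decoy replicate 3. Osmoprotective targets had 1 of 10 higher and 4 lower (camera adjusted p = 0.228, fry adjusted p = 0.00321), with Slc6a12 2.35-fold higher and S100a4 4.89-fold lower. Of 14 chemokines 5 rose and 2 fell (adjusted p = 0.435), and Ccl4 rose 3.82-fold, with both probes called, and Cxcl10 2.04-fold. Vegfc was 1.91-fold higher, in a list of inflammatory targets with 3 of 10 higher and 1 lower (adjusted p = 0.363). The calls of Slc6a12 and Vegfc were lost under median scaling. Il1rn, the interleukin-1 receptor antagonist, rose 3.94-fold and Atf4 fell 3.44-fold, each on both probes.

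Both treatments were then set side by side, since genes changed by both were the stated aim. In both comparisons 2648 features rose and 2907 fell, and 19 were called in opposite directions. The last count was 7, 4 and 8 without control replicates 1, 2 and 3, and 4 for changes of at least 1.5-fold. Lists of these sizes drawn independently would share 770 rising and 775 falling features. Ezh2, Hnrnpa2b1, Zc3h13, Ifi207, Srek1, Ddx5, Hnrnpk and Gsn led the shared rises, and Bcl2a1b, Ptpre, Wdr89, COX2, Yipf2, Bcl2a1d, Mcm7 and Ndrg2 the shared falls. On its other probe, the one above background on all 9 arrays, Yipf2 was higher in the knock-down (0.434 in log2, adjusted p = 0.018) and not called in the decoy (0.233). With the mean over its probes Mcm7 was not called in the knock-down (-0.5, adjusted p = 0.0759) or in the decoy (-0.244, adjusted p = 0.404). Gsn, for gelsolin, was at least 4.68-fold higher in the knock-down and at least 4.61-fold higher in the decoy. Of 3144 genes with 2 probes above background, 190 rose and 183 fell with both probes in both comparisons. Picked after their values were seen, Usp18, Nsdhl, Rbbp7 and Eef2 had the largest such rises, and Ncapd2, Scimp and Smc5 the largest such falls. The 4 genes named for opposite calls were Cxcl14, Hpgds (a prostaglandin D synthase) and Clstn3, lower in the knock-down and higher in the decoy, and Acy1, which was the reverse. Under median scaling the rises of Cxcl14, Hpgds and Clstn3 in the decoy and of Acy1 in the knock-down were not called. Their differences were then -0.114, 0.0161, -0.125 and -0.17 in log2, so Cxcl14, Clstn3 and Acy1 no longer had opposite signs in the treated groups. Relative to the median of all features the values were 0.259, 0.389, 0.248 and 0.258. The fall of Acy1 in the decoy was not called without control replicate 2, control replicate 3 or decoy replicate 3 (adjusted p = 0.0677, 0.0663 and 0.0702), nor the rise of Clstn3 with the mean over its probes (adjusted p = 0.108). In the knock-down comparison 1 of the 2 other probes of Acy1 opposed the call, and the mean over its probes was lower, not higher (-0.239, adjusted p = 0.147).

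Across features the 2 effects correlated with r = 0.897, and features are not independent replicates. Both comparisons use the same control arrays. Unchanged groups simulated against shared controls gave a mean r of 0.499 and at most 1 shared call in 100 simulations, and the covariance was 0.304 against 0.0138 simulated. The simulation drew features independently and gave all groups the same SD. The measured control arrays varied less (median SD 0.091, against 0.22 and 0.18), so the simulated values are not matched to these data. With separate control arrays, 1 for one treated group and 2 for the other, r was 0.862 to 0.874 over the 6 ways (chosen after the data were seen). A shift common to all 3 control arrays would remain in these values. By the moderated F test 8629 features differed among the 3 groups.

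**Figure D2:**
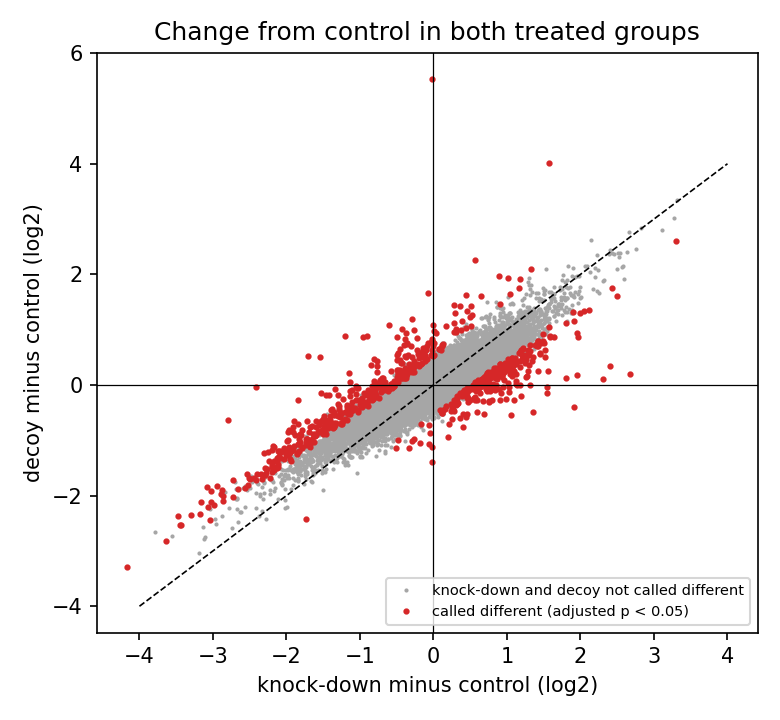
Log2 change from control of each of 18830 features in the knock-down (horizontal) and in the decoy (vertical), with the 687 features that were called different between knock-down and decoy in red and equality as a dashed line. The points lie along the diagonal (r = 0.897), and 19 features were called in opposite directions.

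The third comparison, knock-down against decoy, tests whether the 2 effects differ and does not involve the control levels. Higher in the knock-down were Acot1, an acyl-CoA thioesterase (at least 2.57-fold), Emp2 (4.62-fold), Neo1 (4.14-fold), Itgb7, an integrin subunit (3.42-fold), Dmpk (3.20-fold), Abhd14b (3.20-fold), Acy1 (3.04-fold) and Prr7 (at least 1.78-fold). Lower in the knock-down were Scn11a (5.47-fold), Tmem176b (5.19-fold), Rhox5 (4.70-fold), Rcsd1 (4.48-fold), the chemokine Cxcl14 (4.24-fold), Acod1, which makes itaconate (4.13-fold), Clstn3 (3.54-fold) and Hpgds (at least 2.47-fold). Both probes of Acod1, Cxcl14 and Hpgds fell. In all, 687 features passed, 279 higher and 408 lower in the knock-down. In 29 genes both of the brightest probes were called, and 0 of these pairs disagreed (interval 0 to 11.9%). The count changed with the fit and with the scaling. It was 222 with only the 2 groups compared in the fit, without the less variable control arrays, and 44 under median scaling. With 1 array left out it ranged from 213 (without decoy replicate 1) to 1566 (without knock-down replicate 1).

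A total of 4 gene lists were called, all lower in the knock-down than in the decoy. NRF2 targets had 5 of 18 lower (median -0.23, camera adjusted p = 0.000599, adjusted p = 0.148 with an estimated correlation), with Ftl1 1.87-fold, Prdx1 1.72-fold and Slc7a11 1.70-fold lower. Oxidative phosphorylation genes had 3 of 50 lower (median -0.20, adjusted p = 0.000599, adjusted p = 0.0709 with an estimated correlation). NF-kB and LPS-response genes had 3 of 21 lower (median -0.11, adjusted p = 0.00394, adjusted p = 0.119 with an estimated correlation), namely Acod1, Il1rn (2.13-fold) and Cd83 (at least 1.20-fold). Its median was -0.233 without knock-down replicate 2 and -0.00627 without knock-down replicate 3. Ribosomal protein genes had 2 of 46 lower (median -0.097, adjusted p = 0.0261, adjusted p = 0.488 with an estimated correlation). The ribosomal list was not called without knock-down replicate 3 (median -0.0388, adjusted p = 0.227), without decoy replicate 1 (adjusted p = 0.0520) or with the mean over the probes of a gene (adjusted p = 0.0875), and its median was -0.191 without knock-down replicate 1. Nor was the NF-kB list without the dimmest array of each treated group (adjusted p = 0.0531). Interferon-stimulated genes were not called (median 0.0051, adjusted p = 0.904). Pro-apoptotic genes had 3 of 21 higher and 0 lower and were not called (adjusted p = 0.386), with Fas 2.01-fold and Bcl2l11 1.89-fold higher. Of 30 lysosome genes 3 were lower and 1 higher (adjusted p = 0.583). Of these Ctsb (1.54-fold) and Gpnmb (1.63-fold, with all 3 other probes called the same way) were lower, calls that were lost under 5 and 11 of the alternative settings. Under median scaling Acy1 (1.39 in log2), Cd83 (-0.80), Fas (0.738), Bcl2l11 (0.635), Ftl1 (-1.13), Prdx1 (-0.928), Slc7a11 (-1), Ctsb (-0.76) and Gpnmb (-0.862) kept their direction and were not called.

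**Figure D3:**
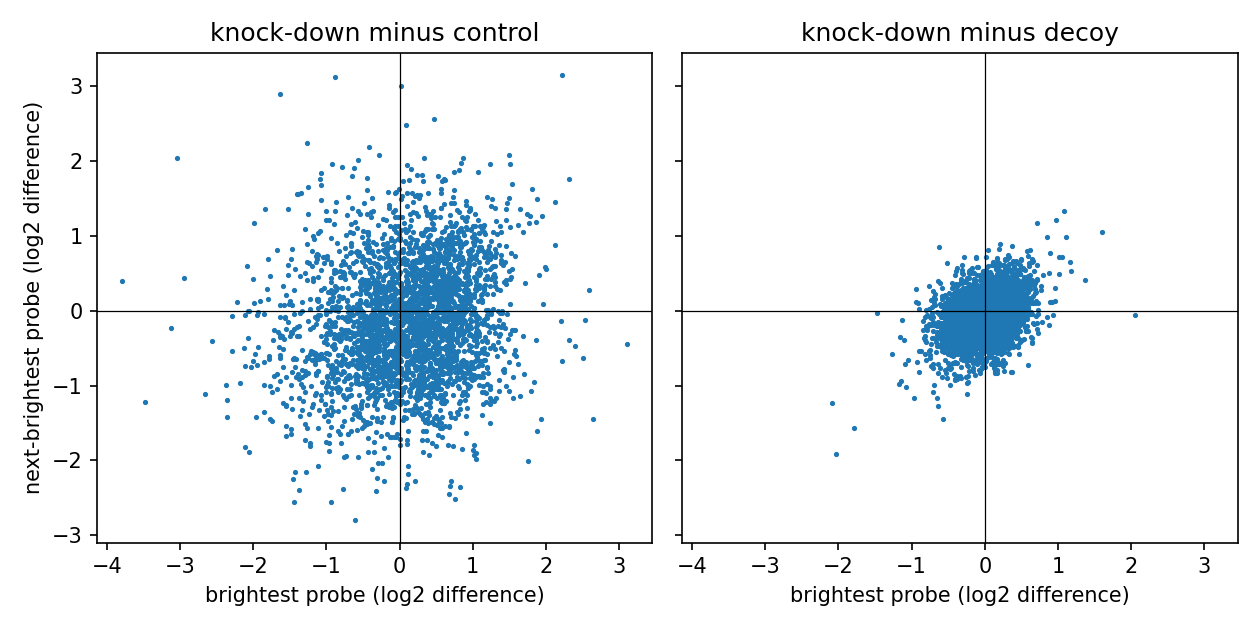
Log2 difference on the brightest (horizontal) and next-brightest probe (vertical) of each of 3144 genes, for knock-down against control (left) and knock-down against decoy (right). The values correlate with r = 0.161 on the left and 0.362 on the right.

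**Figure D4:**
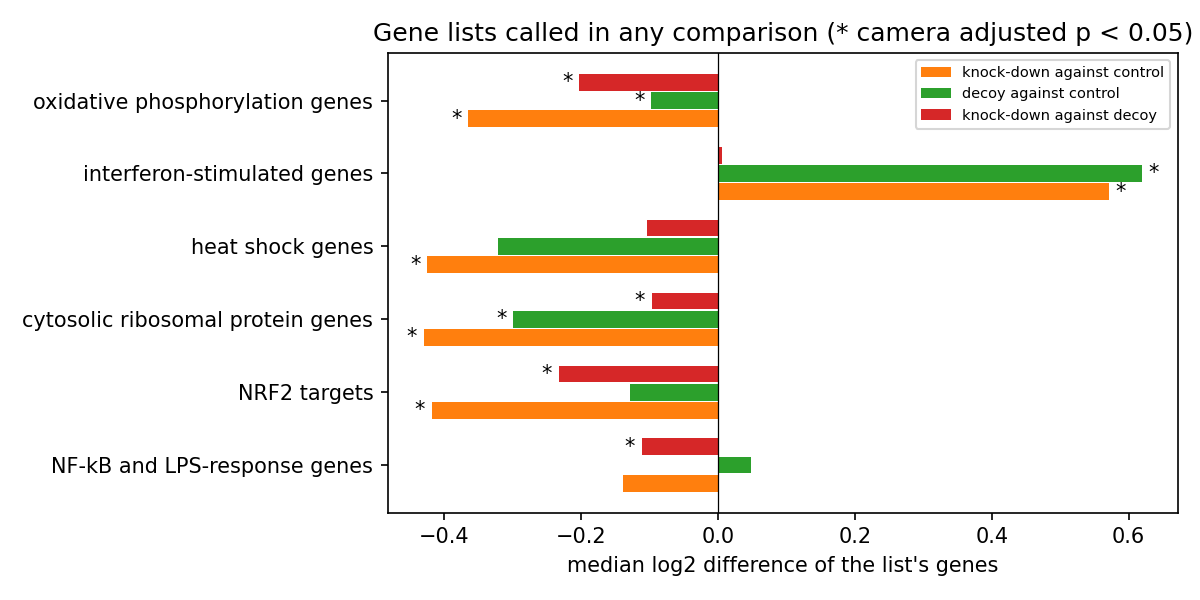
Median log2 difference of the measured genes of the 6 lists called in any comparison, with an asterisk where the camera adjusted p was below 0.05. Interferon-stimulated genes are at 0.57 and 0.62 in the treated groups against control and at 0.0051 between them.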

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

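Apart from the comparison with brightness as a covariate and the counts over drawn splits of the arrays, the tests in this part were chosen after the result was seen. The rule that sets the interval of the probe-pair test was also written after its values were known.

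The effects of knock-down and decoy, each against the same control, differed for 42 of 84 named genes followed here. The test was knock-down against decoy (limma adjusted p below 0.05). Part of these genes were named for their difference in this same comparison, so the count measures no rate. Over all features 3.65% were called (687 of 18830). Differences in log2 were -2.45 for Scn11a, -2.38 for Tmem176b, -2.23 for Rhox5, -2.16 for Rcsd1, -2.09 for Cxcl14, -2.04 for Acod1, -1.82 for Clstn3 and -1.79 for Hpgds. They were -1.32 for Ccl3, -1.13 for Fcgr1, -1.12 for ND1, -1.10 for Ndrg2, -1.09 for Il1rn, -0.945 for Cd83, -0.907 for COX2, -0.903 for Ftl1, -0.849 for Hspe1, -0.825 for Pcna and -0.818 for ATP6. They were -0.786 for Prdx1, -0.762 for Slc7a11, -0.752 for Hspd1, -0.731 for Atp5a1, -0.706 for Tkt, -0.705 for Gpnmb, -0.622 for Ctsb, -0.609 for Mcm7, -0.564 for Rpl32 and -0.542 for Nfat5. Differences in the other direction were 2.30 for Acot1, 2.21 for Emp2, 2.05 for Neo1, 1.84 for Prr7, 1.77 for Itgb7, 1.68 for Abhd14b and for Dmpk, 1.60 for Acy1, 1.37 for Cxcl16, 1.01 for Fas, 0.916 for Bcl2l11, 0.694 for Zc3h13 and 0.692 for Hspb7. For Acot1, Prr7, Hpgds, Fcgr1 and Cd83 the dimmer group was not above background, so only folds of at least 2.57, 1.78, 2.47, 1.59 and 1.20 are measured. Median scaling ended 24 of these 42 calls, 18 of them with a larger difference and 22 with a larger standard error (median 0.231, before 0.154). The calls of Mcm7 and Nfat5 were lost under 12 alternative settings, of Gpnmb and Rpl32 under 11, of Zc3h13 under 9, of Hspd1 under 6, of COX2 and Ctsb under 5, and of Ccl3, Hspb7 and Tkt under 4. Single genes were not followed in the fit with only the groups compared, which gave 222 calls, so it is not among these settings. Of the lists, the median difference between knock-down and decoy over the members was -0.233 for NRF2 targets, -0.203 for oxidative phosphorylation genes, -0.111 for NF-kB and LPS-response genes and -0.0968 for cytosolic ribosomal protein genes.

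Both treated groups differed from control in many genes, largely the same ones. Calls among probes near background are argued against as the whole source for knock-down against control, since 4478 of the 8917 calls were at probes above background on all 9 arrays. Another 1636 were at probes above it on 0 arrays, so part of the calls stays open to it. The share called was 66.2% with only probes above background on all 9 arrays and 47.4% over all features. These shares alone decide nothing, as that filter drops genes that fell to background. A probe-dependent difference of the control set has the values it needs: 41% of the genes with both brightest probes called had them in opposite directions. That share was computed on quantile-normalized values only, so it cannot part a difference between the samples from an effect of the normalization. A response of the cells shared by both treated lines may be present beside it, as the effects correlated with r = 0.897 against at most 0.513 simulated with the same SD in all groups. These cannot be told apart from handling of the control set, because no line analysed here carried an unrelated reagent and array brightness followed the groups.

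Interferon-stimulated genes were higher in both treated groups. A probe-dependent difference of the control set is argued against for this list: the next-brightest probes of its 9 genes with 2 probes had a median change of 1.49 for knock-down against control, where random lists of such probes gave -0.754 to 0.485. The brightest probes of these genes had a median of 0.464, so the size of the rise differed between probes. The same test argues against nothing for the ribosomal list (0.0256, random lists -0.665 to 0.377) or the oxidative phosphorylation list (-0.563, random lists -0.615 to 0.303) for knock-down against control. For decoy against control the ribosomal value was 0.00274 (random lists -0.518 to 0.286). The oxidative phosphorylation value of -0.485 lay just outside its range (-0.472 to 0.243). As the brightest probes of the same genes had a median of 0.101, in the other direction, this does not count against such a difference. A response to the nucleic acid introduced may account for the rise, and a response to lower NFAT5 activity stays open and untested. The larger adjusted p of the list against control was 2.78e-05, which does not exclude the former, and the list's median between knock-down and decoy was 0.0051. These explanations cannot be told apart here without a line carrying an unrelated reagent.

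Knock-down and decoy differed in 687 features. A probe-dependent difference between the arrays is argued against only for the 29 genes with both brightest probes called. Of these pairs 0% were called in opposite directions (interval 0 to 11.9%). That interval lies under the 20% set for such a difference, though 29 genes are too few to place it under 5%. Array brightness by the upper quartile of signal overlapped between the groups (257, 241 and 209 in the knock-down, 237, 236 and 214 in the decoy). A covariate for it could therefore hardly move the size of these differences. With that covariate 1355 features were called and 100% of the 687 stayed called in the same direction, from which no conclusion is drawn. Median scaling, however, left 44 calls, and a biological difference between hairpin and decoy stays open and untested.

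For each comparison of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real split called 8917 features for knock-down against control (1 split of 10 as large, highest other 0), 6530 for decoy against control (1 of 10, highest other 0) and 687 for knock-down against decoy (1 of 10, highest other 219). The lists called were 5 (2 of 10 splits as large, highest other 5), 3 (2 of 10, highest other 4) and 4 (1 of 10, highest other 3). Over 100 splits drawn from 840, 1 gave as many shared calls as the real 5555 and 1 as many opposite calls as the real 19 (highest other 5318 and 0). Over 100 of 280 splits, 1 gave as many features by the F test as the real 8629 (highest other 7151). Chance is thereby excluded only for a grouping of all 9 arrays, and only if these are independent samples, which the labels do not say. The high values of other splits came from those that kept the control arrays together, and splits that parted them reached at most 32 shared calls and 38 by the F test, so these counts reflect the separation of the control arrays. With the control arrays kept as control there are 10 splits of the treated arrays, too few for a share under 0.05. The highest others among these were 5496 shared calls, 3 opposite calls and 8457 by the F test.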

How the results depend on the processing

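Filters on detection p under 0.01 and fits with slides as a block could not be run, as the raw table holds neither. Filters on the background limit, every probe as a feature, both brightest probes, lists on the mean of probes, both dimmest arrays left out, separate control arrays and the brightness covariate were chosen after seeing the data. Of named genes outside the main results, 2746 values kept direction and side of the threshold, 127 lost the call and 7 reversed. Of the named lists' values 384 kept both, 28 lost the call, 9 gained it and 6 reversed. Signal over background limits what can be measured in the treated groups.

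The cause of the following changes was not tested, except where the alternative tests fewer features or asks for a larger change. Median scaling gave 44 calls for knock-down against decoy, 8509 shared and 8 opposite calls and a correlation of 0.949. Relative to the median of all features, NF-kB and LPS-response genes were at -0.129 for decoy against control and interferon-stimulated genes at -0.0356 for knock-down against decoy, both reversed and neither called. Array weights gave 375 calls for knock-down against decoy and 35 opposite calls, and only the groups compared gave 222 for knock-down against decoy. A change of at least 1.5-fold left 5662 calls for knock-down against control, 3928 for decoy against control, 3273 shared and 4 opposite. Without background correction 7 lists were called for knock-down against decoy, and without a filter the correlation was 0.883. With an estimated correlation 0 lists were called for knock-down against control, 0 for decoy against control and 0 for knock-down against decoy.

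With the mean over the probes of a gene, Nfat5 was at 0.0183 for knock-down against control (adjusted p = 0.91) and 0.149 for decoy against control (adjusted p = 0.336). That mean includes 2 Nfat5 probes that were not above background on any array. Acy1 (-0.239), Bcl2l2 (-0.0718) and Hspd1 (0.628) also reversed for knock-down against control, where 3 lists were called. Above background on all 9 arrays gave 4697, 3628, 3284 shared, 8 opposite and 4674 calls by the F test, a correlation of 0.918 and 7 lists for knock-down against decoy. Yipf2, on another probe, was then at 0.434 and 0.233 against control, and interferon-stimulated genes had a median of 0.0342 for knock-down against decoy with the test pointing down. Above background on at least 3 arrays gave a correlation of 0.91 and 3 lists for knock-down against control. Of 5350 genes with 2 kept probes, near background or not, both brightest were called in the same direction in 827 for knock-down against control, 538 for decoy against control and 32 for knock-down against decoy, with 406 shared and 1 opposite. Without the dimmest array of each treated group there were 32 opposite calls, 3 lists for knock-down against control, 2 for knock-down against decoy and a correlation of 0.862. The brightness covariate gave 1355 calls for knock-down against decoy, and separate control arrays a median correlation of 0.868.

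Leaving out 1 array at a time gave 6876 to 9368 calls for knock-down against control, 4391 to 7354 for decoy against control, 3771 to 5768 shared and 6185 to 9276 by the F test. For knock-down against decoy it gave 213 (without decoy replicate 1) to 1566 (without knock-down replicate 1), and 389, 374 and 380 without control replicates 1, 2 and 3. It was 324 without knock-down replicate 3 and 324 without decoy replicate 2. Opposite calls ranged from 4 (without control replicate 2) to 26, with 7, 8 and 11 without control replicates 1 and 3 and decoy replicate 2. The lists called for knock-down against control ranged from 3 (without knock-down replicate 3) to 5, and the correlation from 0.872 to 0.898. Nfat5 in decoy against control ranged from -0.539 to -0.428, where the call was lost without control replicate 1. The interferon list in knock-down against decoy ranged from -0.0276 to 0.0529, uncalled in each.

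Same-numbered arrays showed no common pattern of deviation (correlations from -0.217 to 0.285), which cannot exclude that the numbers pair the samples. In both treated groups the upper quartile of signal fell with the replicate number. With a replicate block there were 8757 calls for knock-down against control, 6304 for decoy against control and 583 for knock-down against decoy. For knock-down against decoy the block ended the calls of Nfat5 (adjusted p = 0.0538) and Rpl32 (adjusted p = 0.0505) and brought in heat shock genes (adjusted p = 0.0472). It changed no other call of a named gene or of the 7 lists followed here.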

Other observations

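Other lists held called genes in both directions without a call of the list. For knock-down against control, 14 of 33 amino acid response and ER stress genes fell and 6 rose (median -0.30, camera adjusted p = 0.151). Lysosome genes had 12 of 30 higher and 10 lower (adjusted p = 0.907), and genes of cell adhesion and matrix remodelling 10 of 35 higher and 12 lower (adjusted p = 0.605). Of 19 p53 targets 8 rose and 3 fell (adjusted p = 0.299), and of 18 cholesterol synthesis genes 7 rose and 4 fell (adjusted p = 0.604). Osteoclast genes, of interest because this line can form osteoclasts, had 7 of 18 higher and 7 lower (adjusted p = 0.898). Of 6 lymphocyte markers 0 were called.

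Between knock-down and decoy, 29 genes were called with both of their brightest probes. Chosen after their values were seen, those higher in the knock-down included Mapk12 (1.08 and 1.34 in log2) and Flot2 (0.979 and 1.22). Those lower in the knock-down included Panx1, a channel gene (-0.969 and -1.16), and Fh1, the fumarate hydratase (-0.894 and -0.813).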
